A study of Drosophila melanogaster with 3 samples.

How the data were processed

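Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in Drosophila melanogaster embryos aged 0 to 14 hours, of both sexes, per the labels. The flies carried a stable transgene that encodes the product of the gene CG17186 with green fluorescent protein (GFP) fused at its C-terminus, and an antibody against GFP recovered the tagged protein with its DNA. The chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. There were 3 biological replicates in 1 group and no second group. A control library is named in the labels as a possible match and was not analysed here.

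The deposited files were peak lists in the narrowPeak layout with 10 columns and no header. Per the read-me tables deposited with each sample, the authors called a relaxed list of peaks and background on each replicate against a control alignment. A further relaxed list came from the 3 replicate alignments pooled, and a thresholded list came from the irreproducible discovery rate (IDR) procedure applied to the replicate lists and the pooled list. The last is called the reproducible set here. Each list existed for the genome builds dm6 and dm3, per the same tables. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of each peak is the value the authors deposited in column 7, and its scale is that of the unnamed caller. It was used to rank and describe peaks within a list. Between replicates it was compared by rank or relative to each replicate's median, and between builds as it was given. The deposited −log10 q-value of each peak (column 9) was read as the authors gave it and entered no test. The files hold no read counts, so the sequencing depth of each replicate is unknown, and the intervals given below cover the number of peaks, genes or summits only.

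In dm6 the replicate lists held 30000, 26139 and 30000 peaks for replicates 1, 2 and 3, the pooled list 23428 and the reproducible set 3814. The dm3 lists held 26270, 19202, 28347, 19310 and 4133 peaks in the same order. The dm6 reproducible set was identical to the 3814 pooled peaks with the largest signal (16.3% of the pooled list), and the dm3 set to the 4133 strongest (21.4%). Overlap of that set with the replicate lists is therefore overlap of the strongest pooled peaks, and the pooled list contains the replicates' own reads. Median peak width was 456, 440 and 450 bp in the replicate lists and 410 bp in the reproducible set; 16 reproducible peaks had the same interval as another and differed in their summit. All positions are dm6 unless dm3 is named, and no coordinate was moved from one build to the other.

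Gene models came from the Ensembl release 115 annotation (FlyBase 6.54; 13945 protein-coding genes on the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4), and sequences from the dm6 reference assembly. A peak was shared when it overlapped by at least 1 bp. For each replicate the signal of the strongest overlapping peak was taken, divided by that replicate's median over the peaks shared by all 3, and averaged; this relative signal is given as mean ± SD over 3 replicates. Overlap with all 3 lists was set against 100 random placements that kept chromosome and width (one-sided permutation test, smallest possible p 0.0099). Summits were assigned to a promoter (within 500 bp of an annotated transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, intron, other exon or intergenic sequence, in that order, and compared with 1000 random placements on the same chromosomes (two-sided permutation test, smallest possible p 0.002). A gene counted as bound when a summit lay within 500 bp of any of its TSSs. Bound shares of 18 gene lists, and of genes in head-to-head pairs with TSSs within 1000 bp, were compared with all other coding genes by two-sided Fisher's exact tests. Exact Clopper-Pearson 95% intervals are given for shares, and exact Poisson intervals for peak densities. The share of peaks on X was compared with its share of length and of coding genes by exact binomial tests.

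For sequence, 17 motifs of known promoter and insulator factors and all words of 8 bases were searched on both strands within 50 bp of each summit and in windows of the same width centred 300 bp to either side. Exact McNemar tests compared the summit with each flank and the larger p was kept. The 8-base word with the highest z score on 2L, 2R and X was tested on 3L, 3R and 4, and the reverse. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05. Peaks, genes and summits are not biological replicates, so these p-values describe the peak set and not the spread between embryo collections. The lists, motifs, main tests and the alternatives behind 285 planned comparisons were fixed before the data were examined; those behind a further 77 comparisons, and the tests said to be chosen later, were not. Of the written list members, 3 symbols had no single match in the annotation and were left out: 1 each in the neural, insulator and germline lists.

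Named genes followed a rule set in advance: the gene with the nearest coding TSS to each of the 25 strongest reproducible peaks found in all 3 replicate lists, the tagged gene, and up to 4 bound members of each fixed list with the largest signal. One item that this rule names is not reported here. The split into the 100 strongest peaks and the rest was chosen after the fall of the signal with rank was seen. The location, list, word and overlap statistics were tested on simulated data at the size of the real set. A planted promoter share of 56.7% was recovered as 56.6% over 3814 peaks, and a planted word was recovered on both sets of arms. Of gene lists planted with a raised bound share, 28 of 30 were called among 13945 genes, and 4 of 200 unplanted ones. These calls used an unadjusted p under 0.05, and each simulated list was longer than any fixed list that gave no call. They do not measure the power for those shorter lists. Alternatives covered the overlap rule, the strength of peaks, single replicates, promoter windows of 250 and 1000 bp, motif windows of 100 bp, flanks at 1000 bp and the dm3 lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.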

Results

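The data describe where GFP-tagged CG17186 was recovered on the genome of fly embryos in 3 biological replicates. CG17186 is annotated only as an uncharacterized protein, and the labels give no treated or control group. The comparisons the design allows are between replicates, and between the peaks and the rest of the genome. The reproducible set held 3814 peaks, and the depth behind each replicate is unknown because the files give no read counts.

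The strongest peaks lay at promoters, several of them of ribosomal protein genes, and largely the same peaks led in every replicate. The strongest of all was at RpL11, which encodes a protein of the large ribosomal subunit, with a relative signal of 99.8 ± 2.42 times the median shared peak (SD, n = 3). This peak spanned 19441863 to 19442723 on 2R, with its summit 60 bp upstream of the TSS, and ranked 1 in all 3 replicates. It was followed by PheRS-m, a mitochondrial phenylalanyl-tRNA synthetase (2R, 13967836 to 13968852; 76.9 ± 8.64), and Tlk, the Tousled-like kinase (X, 3719532 to 3720265; 72.9 ± 4.33). The differences among PheRS-m, Tlk, Spt20 (72.3 ± 1.16) and betaCOP (71.8 ± 7.16) were smaller than the spread between replicates. Spt20 encodes a subunit of the SAGA histone acetyltransferase complex and betaCOP a subunit of the COPI vesicle coat.

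Ribosomal protein genes were nearest to several of the 25 strongest peaks. Besides RpL11 they included RpL37-1 (relative signal 39.8 ± 3.11), RpL18 (38.9 ± 1.81), RpS18 (38.8 ± 2.76), RpL35A (34.5 ± 1.4) and RpL24 (33.0 ± 2.28). The translation elongation factor subunit gene eEF1gamma had 38.6 ± 1.27, and yps, which encodes a Y-box RNA-binding protein, 58.6 ± 2.49. A further SAGA subunit gene, Sgf29, had 57.8 ± 3.2; its summit at 21293695 on 2R lay between Sgf29 and the ribosomal protein gene RpL29. Further peaks were nearest to ArfGAP3 (38.2 ± 2.32), Vps53 of a Golgi tethering complex (37.2 ± 2.39), the calcium pump gene SPoCk (50.7 ± 4.45) and the nuclear envelope gene LBR (37.3 ± 0.97). The centriole gene asl reached 60.7 ± 3.5 and the complex I subunit gene ND-B14.7 48.5 ± 7.53. Other peaks were nearest to CG13625 (58.1 ± 5.21), CG14545 (54.8 ± 4.54), CG30484 (37.6 ± 1.21), CG13667 (33.1 ± 5.44) and CG11095 (32.6 ± 1.03). Of the 25 summits, 24 lay upstream of the nearest coding TSS and 23 within 100 bp of it, with a median offset of -54 bp.

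The signal fell steeply with rank. The pooled signal was 17743 for the RpL11 peak, 5782 for the peak of rank 25 at CG11095, 2402 at rank 50, 692.4 at rank 100 and 109.3 at the weakest peak. Between replicates, the 25 strongest peaks had a median coefficient of variation of 6.09%, against 20.0% for the peaks ranked below 100.

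**Figure D1:**
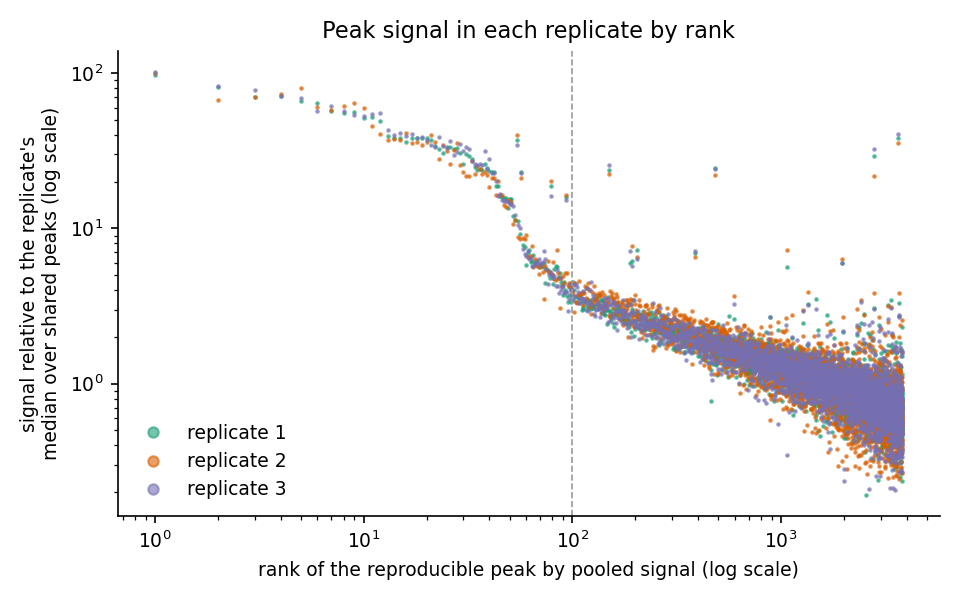
Signal of each reproducible peak in each replicate (vertical axis, relative to that replicate's median over shared peaks, log scale) against its rank by pooled signal (horizontal axis, log scale); each point is 1 peak in 1 replicate and the dashed line marks rank 100. The pooled signal falls from 106 times the median of the reproducible set at RpL11 to 4.13 times that median at rank 100; isolated high points are weaker summits that overlap a stronger peak, whose value they take.

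Nearly all reproducible peaks were found in every replicate. Of the 3814 peaks, 3811 (99.92%) overlapped a peak of replicate 1, 3765 (98.72%) of replicate 2 and 3810 (99.9%) of replicate 3. All 3 lists shared 3758 peaks (98.53%), against a mean of 5.18% and a maximum of 6.06% in 100 random placements (one-sided permutation test, p = 0.0099, the smallest possible). This overlap is largely built in, because the set was thresholded from these lists and from the pooled reads. The test therefore says little about replication. All 25 strongest peaks were among the 100 strongest of each replicate, and 21 were among the 25 strongest of all 3. When each replicate was cut to its own 3814 strongest peaks, the lists shared 76.9% (replicates 1 and 2), 77.6% (1 and 3) and 74.0% (2 and 3), and the share of reproducible peaks in all 3 was 64.39%. Across peaks, which are not independent replicates, Spearman's rho of the signal was 0.705, 0.683 and 0.627 for the same pairs. Among the 100 strongest peaks, from RpL11 down to MEP-1, it was 0.973, 0.985 and 0.968.

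Most peaks lay at promoters and almost none in coding sequence. Of the 3814 summits, 2955 (77.5%) fell within 500 bp of a TSS, against 13.6 ± 0.532% (SD of 1000 placements) by random placement, a ratio of 5.7. Introns held 15.5% of summits against 39.8% by random placement, intergenic sequence 5.77% against 27.1%, 3′ UTRs 0.42% against 4.44%, and coding exons 0.105% (4 summits) against 13.7%. Each of these shares differed from random placement (two-sided permutation test, adjusted p = 0.0028), as did 5′ UTRs (0.341% against 0.783%, adjusted p = 0.0047), though not in the strongest peaks of replicate 3 (0.551%). The share in other exons did not (0.367% against 0.598%, permutation adjusted p = 0.068), though it did in the strongest peaks of replicates 2 and 3 (adjusted p = 0.044 and 0.016). The 3814 strongest peaks of each replicate gave a promoter share of 76.8 ± 1.0% (SD, n = 3), so the excess over random placement was far larger than the spread between replicates. Promoters of coding genes alone held 2890 summits (75.8%), and the median summit lay 47 bp upstream of its TSS.

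**Figure D2:**
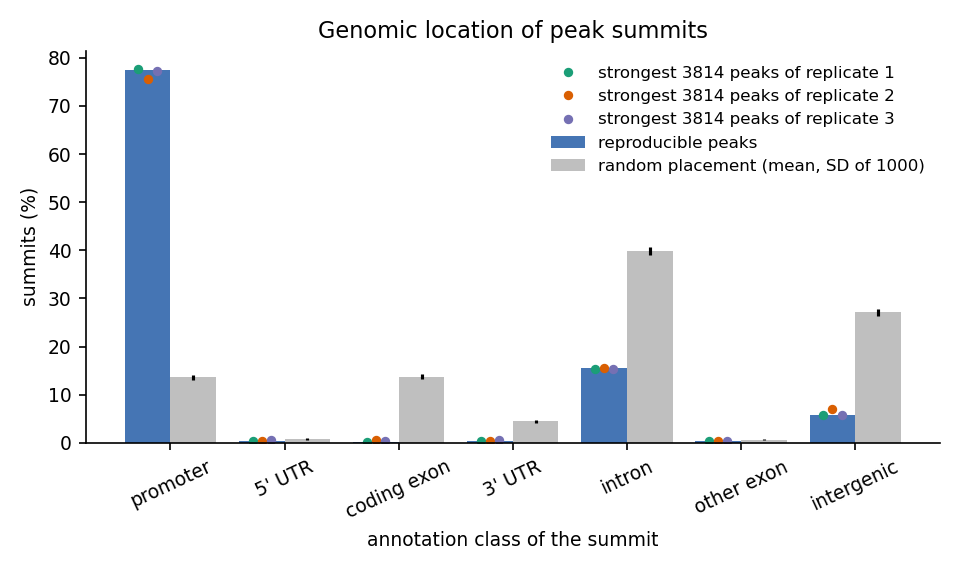
Share of summits in each annotation class (vertical axis, percent) for the reproducible peaks (blue bars), for random placement (grey bars, mean with SD of 1000 placements) and for the 3814 strongest peaks of each replicate (points). Promoters hold 77.5% of summits against 13.6% by random placement, and the 3 replicates lie between 75.7% and 77.6%.

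Promoters of ribosomal protein, cell cycle, translation initiation factor and insulator protein genes were bound more often than those of other genes. Promoters of sensory receptor, cuticle, eggshell and yolk, and segmentation genes were bound less often. In all, 3905 of 13945 coding genes (28.0%) had a summit within 500 bp of a TSS. A summit counted for every gene with a TSS in that window, and the lists were not retested with the nearest TSS only. The list tests and intervals also treat genes as independent, which neighbouring members of a list need not be, so they may be too narrow. Of the 18 fixed lists, 5 were bound more often than the other genes, 5 less often, and 8 did not pass the test. Cytoplasmic ribosomal protein genes came first, with 74 of 92 bound (80.4%, 95% interval 70.9 to 88.0%; Fisher's exact test, adjusted p = 2.6e-24). Their strongest members by this rule were RpL11, RpL29, RpL37-1 and RpL18. Cell cycle and replication genes followed with 19 of 25 (76.0%, 54.9 to 90.6%; exact adjusted p = 3.1e-06). Their examples were PCNA, the replication clamp (signal 543.7), the mitotic kinase gene polo (405.7), the MCM helicase gene dpa (387.9) and the mitotic cyclin gene CycB3 (330.9). Mitochondrial ribosomal protein genes had 41 of 73 bound (56.2%, exact adjusted p = 2.4e-06), led by mRpL3 (3097), mRpS23 (760.3), mRpS10 (741.7) and mRpL21 (600.5). The mRpL3, mRpS23 and mRpS10 summits also counted for the genes Graf, CenG1A and Art3. Translation initiation factor genes had 24 of 44 (54.5%, exact adjusted p = 0.00069), among them eIF6 (489.1), eIF3c (390.0), eIF1 (382.8) and eIF4EHP (346.6). The ribosomal protein gene RpL28 had the same signal as eIF1 (382.8), so they may share a summit.

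Genes of insulator and architectural proteins, which organise chromosome domains and promoters, were bound in 11 of 18 cases (61.1%, 35.7 to 82.7%; exact adjusted p = 0.0067). The chromodomain protein gene Chro had a signal of 896.4 and ranked 80, and pita, a zinc-finger insulator protein gene, 754.1 with rank 92. Cp190, a cofactor of several insulators, had 364.3, and Dref, which encodes the factor that binds the DNA replication-related element, 324.6. Ssl1 had the same signal as Chro (896.4) and the ribosomal protein gene RpL13 the same as Dref (324.6). The Chro and Dref summits may thus count for those genes too.

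None of 59 odorant receptor genes was bound (upper limit 6.06%, exact adjusted p = 2.9e-08), and 1 of 97 cuticle protein genes was (1.03%, adjusted p = 5.9e-12), Lcp9 with a signal of 111.3. Among gustatory receptor genes 2 of 60 were bound (3.33%, exact adjusted p = 4.7e-06), Gr63a (156.2) and Gr97a (148.3). No segmentation gene of 25 was bound (upper limit 13.7%, exact adjusted p = 0.001), and none of 17 genes in the chorion and vitelline membrane list, which includes the yolk protein genes Yp1, Yp2 and Yp3 (upper limit 19.5%, adjusted p = 0.0099). The call for segmentation genes ended in the strongest peaks of replicate 3 alone, where opa and ptc were bound (exact adjusted p = 0.071). In those of replicate 1, 8.0% of segmentation genes were bound and the call held (exact adjusted p = 0.041). The call for the chorion and vitelline membrane list ended in the stronger 50% of peaks (exact adjusted p = 0.17).

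The other 8 lists gave no call. None of 8 Hox genes was bound (exact adjusted p = 0.17), and of 15 dorsoventral patterning genes 1 was, pnr (signal 109.9; adjusted p = 0.14). In the strongest peaks of replicate 1 alone, none of these 15 was bound, and that passed (exact adjusted p = 0.029). Neural development genes had 3 of 15 bound (exact adjusted p = 0.82): the receptor gene N (427.4), elav (365.2) and numb (219.3). The mesoderm and muscle list had 5 of 13 (exact adjusted p = 0.48), with how at 277.7, tin at 176.1 and Mef2 at 161.0. As fixed, that list also counted bib (152.5), which is a neurogenic gene. Proteasome genes had 18 of 48 (37.5%, exact adjusted p = 0.21), led by Rpn2 (339.5), Prosbeta1 (243.6), Prosbeta5 (234.3) and Rpt5 (212.1). Heat shock genes had 3 of 15 (exact adjusted p = 0.82), which were Hsp83 (557.4), Hsp27 (378.8) and Hsp60A (120.1). Germline and maternal genes had 3 of 11 (exact adjusted p = 1.0), namely pum (233.9), exu (181.3) and stau (127.1). Of 6 dosage compensation genes 2 were bound (exact adjusted p = 0.81), msl-3 (149.8) and msl-2 (114.8).

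**Figure D3:**
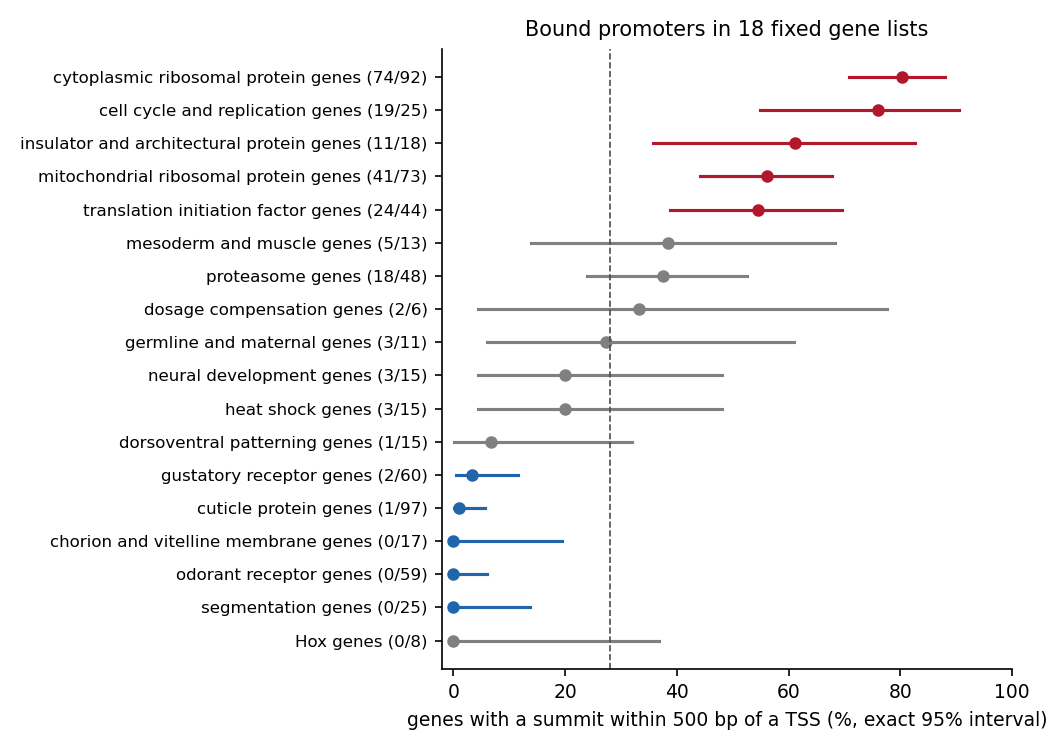
Share of genes bound in each of 18 fixed lists (horizontal axis, percent with exact 95% interval; bound and total genes in brackets), with red for lists above and blue for lists below the other genes at adjusted p under 0.05, grey for the rest, and a dashed line at the 28.0% of all coding genes bound. Cytoplasmic ribosomal protein genes (74 of 92) stand highest, and no gene of the odorant receptor, segmentation, Hox or chorion and vitelline membrane list is bound; the last includes 3 yolk protein genes.

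Genes arranged head to head were bound more often than other genes. Of 4650 coding genes with a partner on the opposite strand within 1000 bp, 2410 were bound (51.8%, 50.4 to 53.3%), against 1495 of 9295 others (16.1%, 15.3 to 16.8%). The odds ratio was 5.61 (Fisher's exact test, p at most 1e-300). The summit between Sgf29 and RpL29 is one example, and the Tlk summit, which also lay within 500 bp of a Rala TSS, is another. Part of this excess is built in, because a summit at the partner's promoter can count for both genes, and counting 1 gene per pair (odds ratio 5.62) does not remove that. With each summit given only to the gene of its nearest TSS, 29.7% of head-to-head genes and 14.6% of the others were bound (odds ratio 2.47, Fisher's exact test, p = 4.7e-95). Both alternatives were added after the data were seen.

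The peaks were spread over all 6 chromosome arms analysed. Chromosome X held 698 peaks (18.3%, 17.1 to 19.6%), against 17.6% of the length (exact binomial test, adjusted p = 0.24) and 15.7% of the coding genes (adjusted p = 4.4e-05). Densities were 29.6 peaks per Mb on X (27.5 to 31.9), between 26.6 and 29.5 on the large autosome arms 2L, 2R, 3L and 3R, and 14.1 (8.49 to 22.0) on chromosome 4, which is small and largely heterochromatic. Per 1000 coding genes, chromosome 4 had 237.5 peaks (143.0 to 370.9) and X 317.9 (294.7 to 342.3).

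Words bound by known promoter factors were concentrated at the summits. The core sequence of the boundary factor BEAF-32, YATCGATA, was within 50 bp of 10.9% of summits (9.91 to 11.9%) against 1.06% of flanks, and the overlapping DREF word TATCGATA of 7.94% against 0.721%. The M1BP word GGTCACACT, found at promoters of ribosomal protein and other housekeeping genes, had 4.93% against 0.393%. Promoter motif 7 (CANCNCTA) had 9.31% against 2.79%, the ZIPIC word CAGGGCTG 2.36% against 0.354%, and the E-box CAGCTG 8.39% against 5.03%. Each of these 6 passed the exact McNemar test (adjusted p between 5.9e-78 and 8.4e-08). A CTCF core also passed (5.06% against 3.63%, exact adjusted p = 0.011) but not in the strongest peaks of any single replicate (adjusted p between 0.075 and 0.51), nor with motif windows of 100 bp (0.42) or flanks at 1000 bp (0.12). GAGA repeats (1.42% against 2.88%) and CA repeats (1.73% against 4.26%) were less frequent at summits than in flanks, with exact adjusted p of 0.00035 and 1.4e-09. Neither passed with flanks at 1000 bp (exact adjusted p = 1 and 0.49), and GAGA repeats did not pass in the strongest peaks of replicate 3 (0.18). The remaining 8 motifs did not pass, among them the Zelda word CAGGTAG (0.472% against 0.524%), the TATA box (3.17% against 2.23%, exact adjusted p = 0.077), the initiator, Pita and Su(Hw). The TATA box passed with motif windows of 100 bp (exact adjusted p = 0.0016), with flanks at 1000 bp (0.036) and in the strongest peaks of replicate 2 (0.009). The GA repeat of CLAMP (0.184% against 0.511%) passed only in the strongest peaks of replicate 2 (exact adjusted p = 0.0049).

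Without any motif chosen in advance, the word with the highest score was ATCGATAG on both sets of arms. Found on 2L, 2R and X, it was at 8.11% of summits on 3L, 3R and 4 (137 of 1689) against 0.444% of flanks (exact McNemar test, p = 7.8e-29). Found on 3L, 3R and 4, it was at 8.19% of summits on the other arms (174 of 2125) against 0.776% (exact p = 3.4e-34).

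The strongest peaks carried another word. In the 100 strongest peaks, a split chosen after the data were seen, the leading word was AACAGCAC on both sets of arms. It was within 50 bp of 54.3% of those summits on 3L, 3R and 4 (19 of 35) and none of their flanks (exact McNemar test, p = 3.8e-06). On 2L, 2R and X it was at 41.5% (27 of 65) against 1.54% (exact p = 1.6e-06). By rank, the word was at 76.0% of the summits ranked 1 to 25, which include RpL11, PheRS-m and Tlk, and at 80.0% of those ranked 26 to 50. It was at 28.0% of those ranked 51 to 75, at none of the 25 ranked 76 to 100 (upper limit 13.7%), and at 0.781% of the 3714 ranked below 100. TATCGATA showed no such concentration, at 3.0% of the 100 strongest and 8.08% of the rest (Fisher's exact test, adjusted p = 0.15). None of the 17 fixed motifs passed within these 100 peaks.

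**Figure D4:**
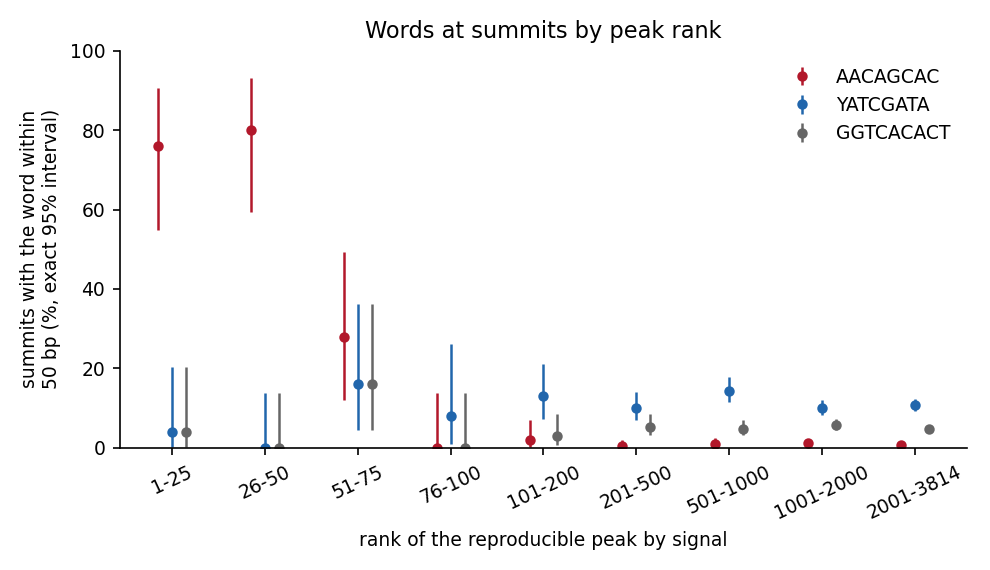
Share of summits with each word within 50 bp (vertical axis, percent with exact 95% interval) by rank of the reproducible peak (horizontal axis, strongest at left), for AACAGCAC, the BEAF-32 core YATCGATA and the M1BP word GGTCACACT. AACAGCAC stands at 76.0% and 80.0% in the first pair of bins and at or below 2.0% past rank 100, while YATCGATA lies between 9.9% and 14.4% past rank 100.

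At the tagged gene itself the peaks were of modest strength. CG17186 lies on the minus strand of 3R (19875974 to 19877514). The reproducible set had 4 peaks within 5 kb of it, none stronger than rank 1499. That peak, with a signal of 190.2 and its summit at 19877541, lay at the 5′ end of CG17186, upstream of the neighbouring gene Arc42. The others were at the 5′ end of Mrp5 (119.5), at the 5′ end of Ask1 (161.8) and within Ask1 (122.6). The relaxed replicate lists held 10, 10 and 14 peaks in the same window.

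**Figure D5:**
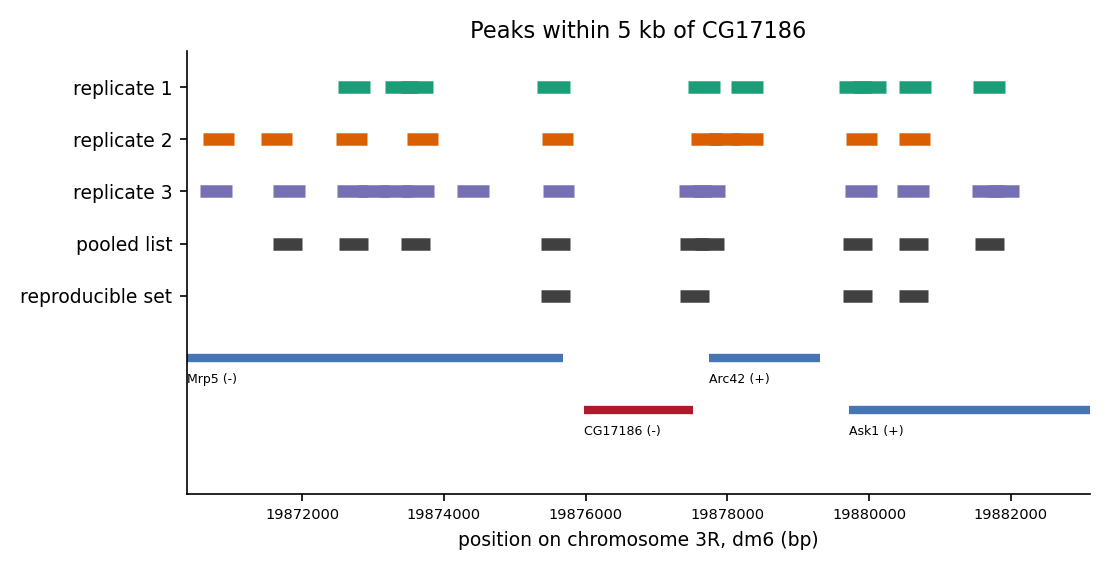
Peaks within 5 kb of CG17186 in the list of each replicate, the pooled list and the reproducible set (bars at their intervals), above the annotated genes with their strand (blue, CG17186 in red); the horizontal axis is the position on 3R in dm6, in bp. The 4 reproducible peaks lie near the 5′ ends of CG17186, Mrp5 and Ask1 and within Ask1.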

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

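The tests in this part were chosen after the values were seen. In the dm3 lists, which entered the comparisons only as an alternative, 99 of the 100 strongest dm6 peaks had a pooled peak on the same chromosome with a signal within 1% of their own. The exception was the dm6 peak at Tlk on X (rank 3), whose signal of 13044 had no such dm3 counterpart. A reproducible dm3 peak with a signal of 118.2 lay outside the 6 arms, at 61019 to 61428 of the heterochromatic sequence XHet in dm3 coordinates. No explanation was tested for either value.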

How the results depend on the processing

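Across 285 planned comparisons of a result with its alternative, 266 counted as unchanged, 11 lost the call, 7 gained one and 1 reversed. A turn of direction counted as reversed only when either value was called, so the 266 include uncalled results that turned. Dosage compensation genes, for example, were 33.3% bound against 28.0% of other genes as reported, and 0.0% bound with the stronger peaks only. The 266 also include comparisons without a test, such as the rank correlation, the number of lists called and the dm3 share on X. The overlap of reproducible peaks with all 3 lists stayed above random placement throughout, at 64.39% with the strongest peaks of each list only, 87.83% with summits within 100 bp, 98.61 to 99.82% with 1 replicate left out and 97.68% in dm3. That overlap is largely built in, as the set derives from the same replicates. The promoter share ran from 71.1 to 82.7% under the planned settings and the odds ratio of head-to-head genes from 4.32 to 6.19; it fell to 2.47 with each summit given to the nearest TSS only, a setting added after the data were seen. Of 10 list calls 8 held under all planned settings (not segmentation genes or the chorion and vitelline membrane list), and of 9 motif calls 6 did (not the CTCF core, GAGA or CA repeats). The reversed result was the DPE, a short degenerate motif, at 94.3% of summits, below flanks at 1000 bp (exact adjusted p = 0.036). Its direction against the nearer flanks was the opposite and not called. Settings added after the data were seen changed more. Within the 100 strongest peaks the mean rank correlation rose from 0.672 to 0.975, 1 list was called (cytoplasmic ribosomal protein genes) and 0 motifs were. In those peaks cell cycle genes (0.0% bound), initiation factor genes (0.0%) and GAGA repeats (2.0% of summits) turned direction without a call; the set is 100 peaks, which limits every such test. Words of 10 bases gave CAGTGTGACC, at 3.02% of held-out summits. It contains the M1BP word GGTCACACT read on the other strand, so it is no separate sequence. Depth is unknown, so whether weak peaks missing from a replicate reflect fewer reads there was not tested.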

Other observations

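Except for the share of promoter words in peaks, the words with 1 mismatch, the TSS windows and the counts at the tagged locus, the tests in this part were chosen after the results they measure were seen. Of 18 further gene families, chosen after the fixed lists were examined, 4 were bound more often than other genes, 6 less often, and 8 did not pass. Nucleoporin genes were bound in 12 of 21 cases (57.1%, Fisher's exact test, adjusted p = 0.013), with Nup154 at a signal of 848.1. Mediator subunit genes had 14 of 25 (56.0%, exact adjusted p = 0.0084) and TBP-associated factor genes, part of the general transcription machinery, 9 of 15 (adjusted p = 0.033). Genes named Cyp with a number, chiefly cytochrome P450 genes, many of which act in detoxification, had 3 of 85 (3.53%, exact adjusted p = 1.2e-07). The strongest of these 3, Cyp1 (signal 348.2), encodes a cyclophilin and not a cytochrome P450. Ionotropic receptor genes had 1 of 60 (1.67%, exact adjusted p = 1e-06) and odorant binding protein genes 1 of 51 (1.96%, adjusted p = 1.2e-05). Those that did not pass (exact adjusted p from 0.053 to 0.78) were genes of mitochondrial complex I, cytochrome c oxidase, ATP synthase, vacuolar ATPase, aminoacyl-tRNA synthetases, translation elongation factors, Vps proteins and Rab GTPases. Within some families a few genes stood far above the rest: ND-B14.7 had 8660 and the next complex I gene, ND-ASHI, 250.3; VhaAC39-1 and Vha14-1 had 5564 and 3950, and Vha55 267.2. The coatomer gene betaCOP had 12690 and alphaCOP 236.4.

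Transfer RNA genes, which RNA polymerase III transcribes, did not differ detectably from random placement in their bound share (9 of 290, 3.1% against 3.01%; permutation test, adjusted p = 1.0). Nor did small nucleolar RNA genes (12 of 269, 4.46% against 2.83%, permutation adjusted p = 0.53). Other non-coding RNA genes had 5.24% against 2.79% (largest placement 3.86%), and transposable elements 0.947% against 2.72%. Both reached the smallest p that 100 placements allow (two-sided permutation test, p = 0.02). Given the other classes tested, their adjusted p could then not fall below 0.067, so this test could not call them. Over 1 kb from a coding TSS, the shares were 2.15% against 2.79% and 0.158% against 2.71%. There the transposable elements again reached the smallest p. Of the 100 strongest peaks, 9 had their summit over 500 bp from any coding TSS. AACAGCAC was in the interval of 4 of these and not in the other 5, of ranks 77 to 89. The strongest, of rank 30 and signal 5175, had its summit in an intron of x16 on 2L, 583 bp from a TSS of nop5, but shared its interval (6918345 to 6919713) with the peak of rank 38 at the nop5 promoter. Away from promoters, an intergenic peak of rank 67 on X (7074340 to 7074774) held the word.

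The 100 strongest peaks held AACAGCAC far more often than the others. It was at 46.0% of those summits (36 to 56.3%) and at 0.929% of the weaker promoter summits (upper limit 1.36%). The word and the split both come from these peaks, so this restates the pattern, and strength at promoters in general stays open. The word alone was not enough for a peak: 18.1% of its 717 copies at promoters lay in a reproducible peak (15.4 to 21.2%), against 7.2% of all promoter bases, and 0.567% of its 4586 copies elsewhere (0.371 to 0.83%), against 0.303% of the bases there. The excess over bases is partly built in, as 62 of the 130 promoter copies in peaks lie in the 100 strongest, where the word was found; below rank 100 it was at 0.781% of summits and 0.498% of flanks (exact McNemar test, p = 0.19). Of the limits set in advance, the 18.1% fell short of the 50% asked of a recognised sequence, and its upper limit was below the 28.0% of coding genes bound, which was to count against one. That last limit was ill chosen, since it counts genes with a summit anywhere within 500 bp, while 7.2% of promoter bases lie in a peak. A recognised sequence is therefore neither supported nor excluded. A candidate explanation is a longer sequence. Flanking bases learned on some arms ranked copies in strong peaks above promoter copies in no reproducible peak on the other arms. The areas under the curve were 0.934 and 0.96 (permutation p = 0.0001, the smallest possible). Copies were not independent, as 8 of the 25 strongest peaks held 2 or more in their interval. The copies in no reproducible peak were not matched to the others for position within the promoter. Some of them lay in a weaker pooled peak, as the pooled list held 228 of the 717 promoter copies.

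In those strong copies, T stood directly before the word in 82.6% (16.2% of promoter copies in no reproducible peak) and C at the third base before it in 66.7% (19.3%). Of the promoter copies of TAACAGCAC, 45.4% (79 of 174) lay in a reproducible peak, and of those of CCTAACAGCAC 84.2% (16 of 19, 60.4 to 96.6%), but elsewhere 1 of the 17 copies of CCTAACAGCAC did. These longer words were read from the strong copies themselves, so their promoter shares are partly built in and do not test the longer sequence. Exact words of 10 bases held up on 1 set of arms only. CGCCTAACAG, found on 2L, 2R and X, was at 2 of 35 strong summits on 3L, 3R and 4 (exact McNemar test, p = 0.5). AACAGCACGC, found on 3L, 3R and 4, was at 11 of 65 on the other arms (exact McNemar test, p = 0.00098). Of the 100 strongest peaks, some of which share an interval, 56 held the 8-base word in theirs. Whether the tagged protein or a partner reads this sequence was not tested, and no biological explanation that needs a second group was tested, since the design has 1 group.

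Of the peaks below rank 100, 75.4% lay at coding promoters, and a minority had words of other factors at the summit, such as YATCGATA (11.0%). For the DREF word, position within the promoter alone is argued against: 50 bp upstream of the TSS, it was at 12.8% of all bound promoters (11.8 to 13.9%) and 3.76% of those with no reproducible peak (3.4 to 4.16%). Words with 1 mismatch to AACAGCAC were as frequent at summits below rank 100 as in flanks (9.37% each, ratio 1.0, exact McNemar test, p = 0.53). This argues against such copies as a general account of the peaks below rank 100. Copies with more mismatches, or weaker copies of a longer sequence, were not tested. TATA boxes went the other way, at 2.97% of bound and 10.4% of unbound promoters (Fisher's exact test, adjusted p = 7.3e-54). Whether these weaker peaks reflect recruitment by other factors, or general recovery of open promoters in the assay, was not tested, and either may hold.

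The replicate lists held several peaks around the tagged gene, where a transgene could add copies of the locus. The number was high for the local gene density, but short of the limit set in advance for it. The 10, 9 and 13 summits within 5 kb (1 fewer than the overlapping peaks in replicates 2 and 3) were compared with 7389 coding genes. Those genes had at least as many coding TSSs within 5 kb, and medians of 6.0, 4.0 and 6.0 summits. The counts lay at percentiles 85.37, 90.7 and 93.06 of them. Each window ran 5 kb beyond both ends of the gene, so longer genes had wider windows, and genes with more TSSs were included. Both can lower these percentiles. They therefore cannot tell whether local density accounts for the number. Peaks away from TSSs within 10 kb lay at percentiles 83.02, 95.83 and 92.43 of coding genes, above the median but short of the limit set in advance. Those genes were not matched for length either. Extra copies from the transgene thus stay open, since the read depth of the locus was not analysed here.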
